A study of Homo sapiens with 6 samples.

How the data were processed

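RNA from 6 cultures of DU-145, a human prostate cancer cell line, was sequenced as polyadenylated, strand-specific libraries. The cells carried a tetracycline-inducible short hairpin RNA against MUC1. Per the labels' protocols, 3 cultures received vehicle and 3 received doxycycline (DOX) for 7 days, and both arms were then exposed to interferon-gamma (IFN-gamma) at 10 ng/ml for 24 hours. Groups and replicate numbers were taken from the sample titles, giving 3 DOX-negative and 3 DOX-positive libraries.

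The deposited table holds 1 whole-number read count per gene and library, not normalized, for 60662 genes, together with a gene length. The submitters' processing notes name CASAVA 1.8.2, STAR 2.7.9a, DESeq2 1.24.0 and the build GRCh38.p7, without a role or an order for any of them. The counting tool, the gene annotation, the treatment of reads shared by several genes and the strand setting of the counting are not given in the sources used here. Genes that overlap others, genes with an antisense partner and members of families with near-identical copies are therefore uncertain, because their reads could have been split or discarded. In the deposited count table, 14 gene symbols had been turned into dates and 66 genes had no symbol. Missing or altered symbols were replaced from the gene ID where an ID table gave one. The 66 genes with no symbol took 0.000516% of all reads. GENCODE 29, on GRCh38, supplied positions and gene types for 58476 of the gene IDs.

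Total counts were 94556595, 138844816 and 87739734 reads in DOX-negative replicates 1, 2 and 3, and 110266613, 150921436 and 105358357 reads in DOX-positive replicates 1, 2 and 3. A count of 3 reads, the level that a count of 0 allows, corresponded to between 0.0199 and 0.0342 CPM (counts scaled to library size) per library. That floor covers counting error only, since the reads carry no molecular identifiers. Replicates were compared by a chi-square test over genes with at least 20 reads in a pair of libraries. Chi-square per degree of freedom lay between 6.40 and 20.8 within groups and between 214 and 285 across groups, so no pair of libraries agreed within sampling noise. The labels speak of triplicate cultures and say nothing of separate days or passages, so p-values measure the spread between these cultures.

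Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term. Genes were kept by the default filterByExpr settings (a minimum count of 10 and a minimum total of 15), which left 24695 genes. Libraries were scaled by TMM, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A positive log2 fold change means higher in DOX-positive cells. Standard errors of log2 fold changes were taken as the absolute fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries.

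The model, the alternatives, the 29 gene lists and the rule for named genes were written before the data were examined. The rule named MUC1 and 12 genes given whatever their result, the 8 genes with the largest change in each direction, and up to 4 members of each list with the smallest p-values. Genes in the 8 per direction had a mean CPM of at least 1, no overlap between the groups and no clone or pseudogene name. Genes outside the rule are marked as chosen after their values were seen. Of what the rule and the lists cover, 1 gene and 1 list, which camera called, are not reported here. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 29 lists.

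Alternatives were DESeq2 size factors, upper-quartile scaling, library size without a composition factor, no filter, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, and each library left out in turn. For lists they were camera with an estimated correlation, fry, the block and each library left out. A count of protein-coding genes alone in the main result, and 10000 random lists matched on expression and gene length, were added after seeing the data. On counts simulated for DOX-positive against DOX-negative over 23938 genes, the edgeR test recovered 52.4% of 63 genes changed 1.5-fold, 77.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold. It called 10 of 23742 genes simulated without a change, which is 0.0421%. The simulation changed a far smaller share of genes than the 56.5% called in the real data, and the adjusted threshold depends on that share. These rates therefore may not carry over to the real result. In a separate simulation camera called the list that had been moved and 0 of 28 random lists at an adjusted p under 0.05. Its counts were drawn independently for each gene, so it did not test the preset correlation. Figures were drawn with matplotlib 3.10.9.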

Results

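The series measured gene expression in DU-145 prostate cancer cells with and without induction of a hairpin against MUC1, which encodes a transmembrane mucin. The title of the series names MUC1-C, type II interferon signalling, chromatin remodelling and immunosuppression as its subject. All 6 libraries came from cells exposed to IFN-gamma, so the comparison asks how IFN-gamma-treated cells differed once DOX had induced the hairpin. It has 3 DOX-negative and 3 DOX-positive libraries, with total counts from 87739734 to 150921436 reads.

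MUC1 (ENSG00000185499.16, chromosome 1, 155185824 to 155192916 on the minus strand, GRCh38) fell from 21.5 ± 0.963 CPM in DOX-negative cells to 1.39 ± 0.123 CPM in DOX-positive cells (SD, n = 3 each). This was a 15.5-fold reduction, with a log2 fold change of -3.96 (SE 0.08, edgeR adjusted p = 5.12e-16). MUC1 read 20.4, 21.8 and 22.2 CPM in the DOX-negative libraries and 1.53, 1.31 and 1.32 CPM in the DOX-positive libraries, which goes with their labels. No unstimulated cells and no DOX-treated cells with a control hairpin were analysed here. The values therefore measure DOX and the hairpin together, and not the response to IFN-gamma.

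In DOX-positive cells 35 of 39 IFN-gamma-induced genes fell, 22 of 28 epithelial genes rose and 26 of 31 cholesterol and fatty acid synthesis genes rose at an edgeR adjusted p under 0.05. As lists, camera called these 3 with a preset correlation, and gave adjusted p = 0.432, 0.346 and 0.517 with an estimated correlation. WARS, the IFN-gamma-inducible tryptophanyl-tRNA synthetase, fell 4.90-fold from 6916 ± 292 to 1413 ± 47.9 CPM. CDH1, which encodes E-cadherin, rose 2.61-fold, and HMGCS1, an enzyme of the mevalonate pathway, rose 2.27-fold. CD274, which encodes the checkpoint ligand PD-L1 and is itself IFN-gamma-inducible, rose 1.49-fold, against the direction of most of its list.

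Of 24695 genes tested, 13957 (56.5%) changed at an edgeR adjusted p under 0.05, with 6825 higher and 7132 lower in DOX-positive cells. At least 2-fold changes were seen for 3196 genes, 879 of them higher and 2317 lower. Among all 24695 genes tested, the 3 values of one group lay clear of the 3 of the other for 15416, and chance gives such separation in 10% of genes. The changed genes, which the test selects for separation, made up 13559 of these. With libraries scaled by their size alone, the median of all genes moved by -0.14 on the log2 scale and the split became 4689 higher and 9579 lower, so small changes are relative to the scaling. The count of at least 2-fold changes was 1357 among genes with at least 1 CPM in 3 libraries.

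Most of the genes chosen in advance for this pathway fell. IFNGR1, the ligand-binding chain of the IFN-gamma receptor, fell 2.31-fold, from 39.3 ± 1.64 to 17.0 ± 0.233 CPM (log2 fold change -1.21, SE 0.04, edgeR adjusted p = 2.74e-13). IRF1, an interferon-inducible transcription factor, fell by 0.45 on the log2 scale from 319.6 ± 20.7 CPM. JAK1, a kinase bound to the receptor, rose from 159.5 ± 6.21 to 248.5 ± 4.85 CPM (log2 fold change 0.64, SE 0.04). IDO1, which degrades tryptophan, fell 2.73-fold, PTGES, a prostaglandin E synthase, fell 2.29-fold, ISG15, a ubiquitin-like modifier, fell 1.96-fold, and SERPINB9, an inhibitor of granzyme B, fell 1.57-fold. The chromatin remodelling subunit PBRM1 fell by 0.28 on the log2 scale (edgeR adjusted p = 2.86e-06). ARID1A, a subunit of the BAF complex, had a log2 fold change of -0.12 (SE 0.03, edgeR adjusted p = 0.00505). That call was lost with DESeq2 size factors (adjusted p = 0.0752), without DOX-negative replicate 3 (0.0854) and without DOX-positive replicate 2 (0.0694), in a range of 1.26e-06 to 0.0854 over the alternatives.

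**Figure D1:**
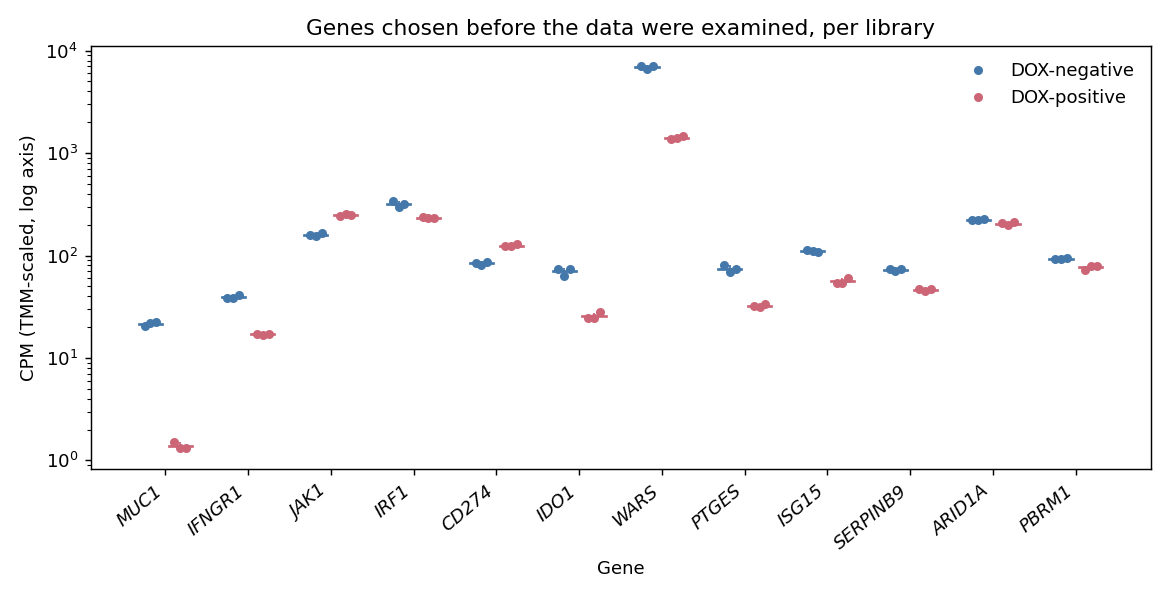
CPM of 12 genes chosen before the data were examined, on a log axis, with 1 point per library, the group mean as a horizontal line and the SD as a vertical line (n = 3 per group). MUC1 drops from 21.5 to 1.39 CPM and WARS from 6916 to 1413 CPM, while CD274 and JAK1 are higher in DOX-positive libraries.

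Of 39 IFN-gamma-induced genes tested, 35 fell, 3 rose and 1 did not pass, with a median log2 fold change of -1.12. CIITA, the master regulator of MHC class II genes, fell 3.56-fold, the complement protease C1S 3.87-fold, and PLAAT4, a phospholipase, 3.25-fold. The 3 that rose were CD274 (0.57), GCH1 (0.44) and FAS (0.25), and ICAM1 had a log2 fold change of 0.05. GCH1, FAS and ICAM1 were singled out after their values were seen. Of 48 antiviral interferon-stimulated genes, 46 fell, 0 rose and 2 did not pass, with a median of -0.96. Among them the dynamin-like GTPases MX1 and MX2 fell 3.17-fold and 5.22-fold, OASL fell 4.73-fold and the helicase DDX60 fell from 136.6 ± 5.13 to 34.1 ± 2.08 CPM. Camera placed both lists below other genes (adjusted p = 1.2e-10 and 6.33e-18), with adjusted p = 0.432 and 0.346 with an estimated correlation. Of 17 receptor and JAK-STAT genes, 11 fell and 5 rose (camera adjusted p = 0.212), and STAT2 fell by 0.89 on the log2 scale.

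Antigen presentation genes were also lower. In the MHC class II list 14 of 18 genes fell and 2 rose, with a median log2 fold change of -0.74. HLA-DRA, an MHC class II chain, fell 5.43-fold from 41.8 ± 0.527 to 7.71 ± 0.588 CPM, the invariant chain gene CD74 fell 3.58-fold, and HLA-DPA1 fell 5.34-fold. In the MHC class I list 17 of 21 genes fell and 2 rose, by smaller amounts, with a median of -0.29. TAP1, a subunit of the peptide transporter, fell by 0.55, the immunoproteasome subunits PSMB10 and PSMB8 fell by 0.73 and 0.56, and the proteasome activator PSME1 fell by 0.43 on the log2 scale. Adjusted over the list alone, 18 class I genes fell. Camera adjusted p was 0.000269 for class II and 0.000297 for class I, and 0.432 and 0.652 as adjusted p with an estimated correlation. Reads of HLA genes can be split among their near-identical copies.

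Immune checkpoint and immunosuppressive genes went both ways, with 12 of 26 higher and 11 lower (camera adjusted p = 0.718). NT5E, the ectonucleotidase that makes adenosine, rose 2.26-fold from 388.3 ± 10.0 to 876.6 ± 14.3 CPM, while WARS and IDO1 fell. CD59, an inhibitor of complement lysis, rose 2.47-fold. Among 25 NF-kappaB and inflammatory cytokine genes, 9 rose and 12 fell (camera adjusted p = 0.62). The NF-kappaB inhibitor TNFAIP3 rose 2.72-fold, while CXCL8 fell 2.27-fold, TNFAIP2 fell 1.93-fold and the chemokine CCL5 fell 12.1-fold.

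Epithelial genes rose in 22 of 28 cases and fell in 4, with a median log2 fold change of 0.77. EPCAM, an epithelial adhesion molecule, rose 3.41-fold from 54.7 ± 0.242 to 186.8 ± 2.03 CPM, KRT19 rose 3.36-fold, and ESRP1, a splicing regulator of epithelial cells, rose 3.89-fold. The list lay above other genes (camera adjusted p = 3.28e-07), with adjusted p = 0.346 with an estimated correlation. Mesenchymal genes were split, with 9 of 28 higher and 14 lower (camera adjusted p = 0.718). The collagen cross-linking enzyme LOX rose 4.65-fold, the transcription factor SNAI2 3.82-fold, ITGA5 1.70-fold and MMP14 1.62-fold. ZEB1 and ZEB2, repressors of CDH1 that were singled out after their values were seen, fell by 0.88 and 2.34 on the log2 scale. Mucin genes fell in 5 of 8 cases and rose in 0, MUC1 included, with a median of -1.27 (camera adjusted p = 0.00541, and adjusted p = 0.346 with an estimated correlation). The hairpin targets MUC1, so its fall was set by the design, and the list was not tested without it. MUC16, which encodes CA125, fell from 126.4 ± 16.0 to 63.4 ± 4.39 CPM, MUC3A fell 2.97-fold and MUC20 fell 3.56-fold.

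Chromatin genes changed in both directions. Of 28 BAF and PBAF subunits, 10 rose and 13 fell (camera adjusted p = 0.649), or 4 and 17 with library size alone. The PBAF subunit ARID2 fell 1.73-fold from 150.9 ± 5.78 to 87.4 ± 2.20 CPM, ARID1B fell by 0.46 and SS18 by 0.41 on the log2 scale, and BCL7B rose by 0.44. Of 32 NuRD, Polycomb and DNA methylation genes, 7 rose and 17 fell (camera adjusted p = 0.427), or 5 and 23 with library size alone. The de novo DNA methyltransferase DNMT3A fell 2.37-fold and MBD3 1.48-fold, while MBD2 rose 1.57-fold and GATAD2A 1.45-fold. Of 13 histone genes whose transcripts normally lack a poly(A) tail, 9 fell and 1 rose (10 fell when adjusted over the list alone), with a median of -0.40. These included the linker histone genes HIST1H1B (-0.97) and HIST1H1D (-1.84). The libraries were of polyadenylated RNA, so these values may not reflect the level of histone mRNA. Camera adjusted p for the histone list was 0.0129, and adjusted p was 0.652 with an estimated correlation.

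Metabolic lists were mostly higher. Of 31 cholesterol and fatty acid synthesis genes, 26 rose and 3 fell, with a median log2 fold change of 0.51 (camera adjusted p = 1.8e-07, and adjusted p = 0.517 with an estimated correlation). HMGCS1 rose from 158.7 ± 8.66 to 360.6 ± 0.956 CPM, IDI1 rose by 0.75 and DHCR7 by 0.71 on the log2 scale, and the fatty acid desaturase FADS1 fell by 0.83. Hypoxia and glycolysis genes rose in 21 of 31 cases and fell in 5 (6 when adjusted over the list alone), with a median of 0.25. The peptide hormone gene ADM rose 4.63-fold and the glucose transporter SLC2A1 1.98-fold, and the glycolytic enzyme PGAM1 fell 2.65-fold. Nuclear-encoded oxidative phosphorylation genes rose in 28 of 39 cases and fell in 3 (30 rose when adjusted over the list alone), with a median of 0.25, and included NDUFA4 (0.53) and ATP5F1B (0.41). Mitochondrially encoded protein genes rose in 12 of 13 cases, with a median of 0.38, and MT-CO2 went from 3325 ± 375 to 4574 ± 97.1 CPM. The mitochondrial share of reads was 4.35%, 5.67% and 4.91% in DOX-negative replicates 1, 2 and 3, and 6.21%, 5.49% and 5.75% in DOX-positive replicates 1, 2 and 3. With library size alone 17 hypoxia and glycolysis genes rose and 8 fell (median 0.11), 20 oxidative phosphorylation genes rose and 7 fell (median 0.10), and 11 mitochondrially encoded genes rose and 0 fell (median 0.24). Camera adjusted p was 0.00541 for hypoxia and glycolysis, 1.1e-05 for oxidative phosphorylation and 0.00854 for the mitochondrial genes, and 0.688, 0.346 and 0.762 as adjusted p with an estimated correlation. Against random lists matched on expression and length, these 3 lists did not pass (adjusted p = 0.070, 0.363 and 0.320).

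Of 42 DNA replication and G1/S genes, 23 rose and 7 fell (24 rose when adjusted over the list alone), with a median log2 fold change of 0.11. With library size alone 10 rose and 15 fell, with a median of -0.03. CCNE1, which encodes cyclin E, rose 1.90-fold and E2F1 rose 1.41-fold, while POLA1 fell 1.41-fold. Of 31 MYC and ribosome biogenesis genes, 17 rose and 6 fell (18 rose when adjusted over the list alone), with a median of 0.14. With library size alone 9 rose and 12 fell, with a median of -0.01. ODC1, the first enzyme of polyamine synthesis, rose 2.68-fold, and LDHA fell 1.84-fold. Camera adjusted p was 0.0156 and 0.0257 for these lists, and 0.652 and 0.432 as adjusted p with an estimated correlation. Against matched random lists the adjusted p was 0.573 and 0.833. Of 41 mitosis and G2/M genes 12 rose and 11 fell, CDC25B and TOP2A among the latter by 0.62 and 0.36 on the log2 scale (camera adjusted p = 0.844), and the split was 3 and 24 with library size alone and 9 and 19 with upper-quartile scaling.

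**Figure D2:**
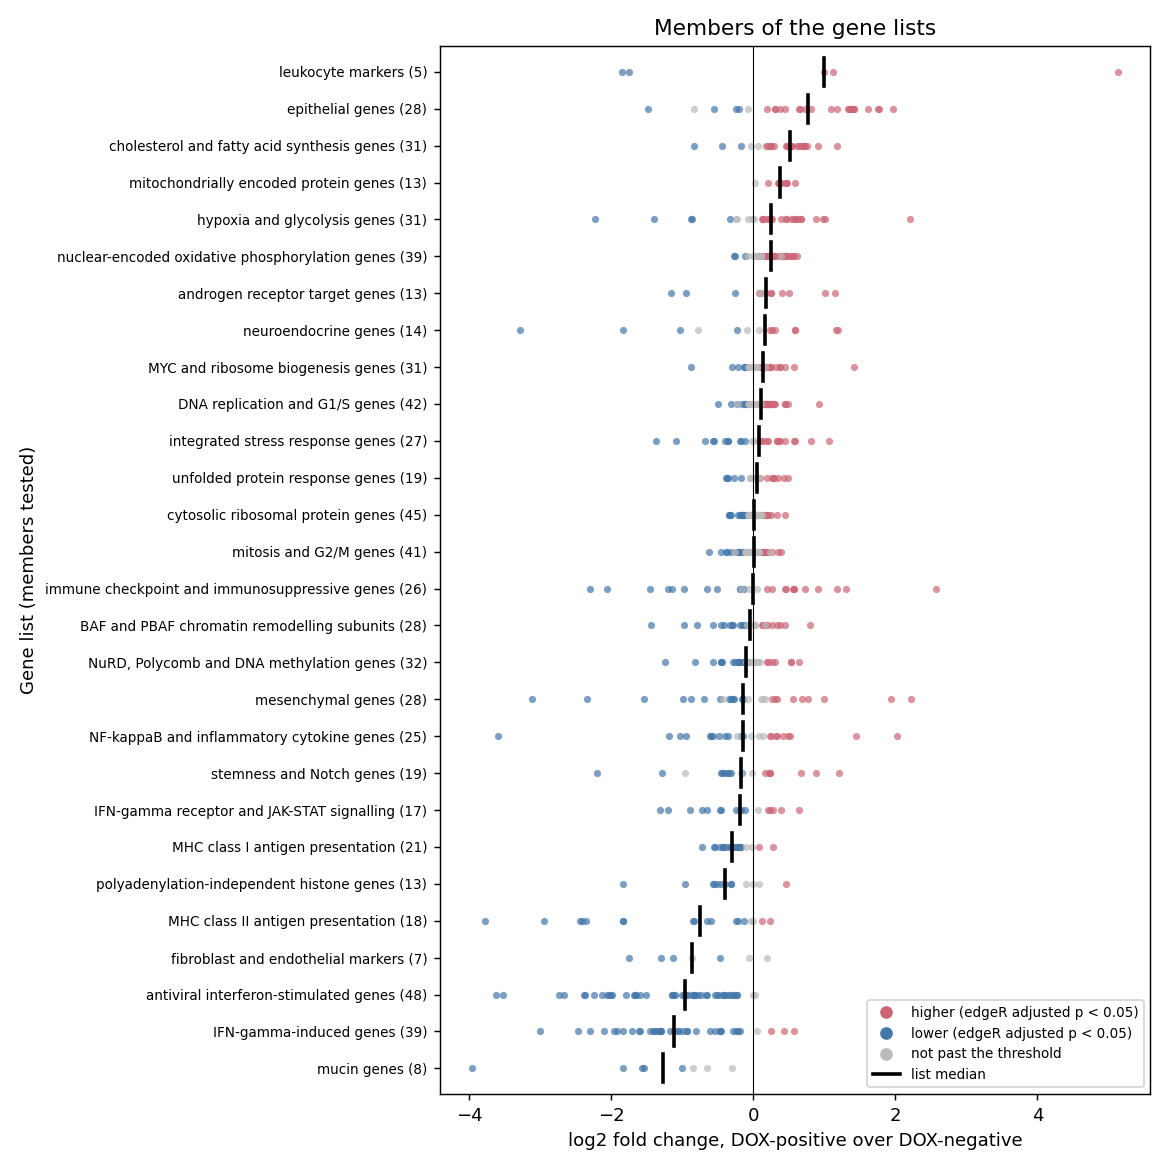
Log2 fold change of each tested member of the gene lists described here, ordered by list median (black bar), with members higher in DOX-positive cells in red, lower in blue and not past the edgeR threshold in grey. The antiviral list has 46 of 48 members lower and the epithelial list 22 of 28 higher.

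The largest increases among genes that met the naming rule were in IL1RL1 and in genes with under 1 CPM in DOX-negative cells. IL1RL1, which encodes the alarmin receptor ST2, rose 24.1-fold from 8.10 ± 0.560 to 195.0 ± 4.31 CPM (log2 fold change 4.59, SE 0.05, edgeR adjusted p = 8.79e-19). CD79A, a subunit of the B-cell receptor, rose from 0.737 ± 0.218 to 25.8 ± 1.10 CPM. ESM1, which encodes the proteoglycan endocan, rose from 0.126 ± 0.0299 to 6.19 ± 0.433 CPM, and ATP6V0D2, a proton pump subunit, rose from 0.121 ± 0.0484 to 3.88 ± 0.114 CPM. MACC1, a regulator of MET expression, reached 2.38 ± 0.0747 CPM, the trypsin inhibitor gene SPINK1 2.08 ± 0.262 CPM and SUN3 1.89 ± 0.104 CPM. MACC1 and SPINK1 read 0.0422 ± 0.0178 and 0.0432 ± 0.0324 CPM in DOX-negative cells, near the floor of 3 reads, so their folds are imprecise. KRTAP2-3 rose from 0.247 ± 0.0703 to 22.4 ± 0.921 CPM, a value that is uncertain because its family has near-identical copies.

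Under the same rule the largest decreases beside MUC1 were in GGT5, AKR1C2, IFITM1, CCL5, SUSD2, IFI44L and CYP4F3. GGT5, a gamma-glutamyltransferase that acts on leukotrienes, fell 39.5-fold from 11.5 ± 0.417 to 0.292 ± 0.0455 CPM. SUSD2, a sushi domain membrane protein, fell from 172.0 ± 9.69 to 14.4 ± 1.37 CPM (log2 fold change -3.58, SE 0.06, edgeR adjusted p = 1.44e-16). IFITM1, an inhibitor of viral entry, fell 12.3-fold, IFI44L 11.5-fold and CYP4F3, a leukotriene hydroxylase, 11.4-fold. AKR1C2, a steroid-metabolizing reductase, fell 13.8-fold, with an uncertain value because AKR1C1 is nearly identical. SUSD2 (24181259 to 24189110) and GGT5 (24219654 to 24245142) are neighbours on chromosome 22 (GRCh38). The pseudogenes GGTLC4P and POM121L9P beside them, named after their values were seen, had log2 fold changes of -3.73 and -4.65. CABIN1 on one side and SPECC1L on the other, also named after their values were seen, rose by 0.21 and 0.14.

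**Figure D3:**
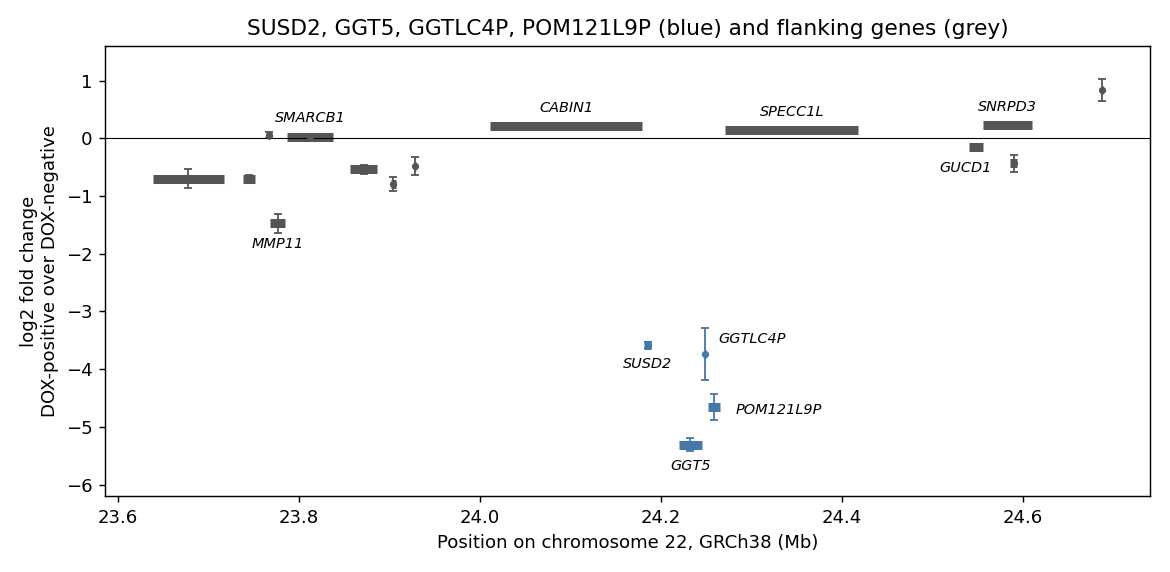
Log2 fold change against position on chromosome 22 (Mb, GRCh38) for SUSD2, GGT5, GGTLC4P and POM121L9P (blue) and for the 14 genes within 500 kb with a mean CPM of at least 1 (grey), where bars span each gene and vertical lines are standard errors. The blue genes lie between -3.58 and -5.31, and the grey genes CABIN1 and SPECC1L on either side at 0.21 and 0.14.

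Across the 29 lists, camera called 8 higher and 6 lower, and 22 lists had the same counts when adjusted over the list alone. With an estimated correlation none of the 14 calls held, with 4 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.346. The mucin list lost its call although its estimated correlation, -0.06, lay below the preset 0.01. A call lost under this setting is therefore not by itself evidence of correlated members. The other called lists did have estimated correlations above the preset, from 0.018 (MYC and ribosome biogenesis) to 0.96 (mitochondrially encoded). The estimate was 0.35 for the IFN-gamma-induced list, 0.30 for the antiviral list and 0.53 for MHC class I. Against random lists matched on expression and length, chosen after seeing the data, 8 of the 14 passed. They were the IFN-gamma-induced, antiviral, both MHC, epithelial, cholesterol, mucin and histone lists. The mucin list includes MUC1, the target of the hairpin, and was not tested without it. Random genes were drawn independently, so this test makes no allowance for correlation among list members. Its p-values can therefore be too small. Lists that camera did not call passed this test as well. The JAK-STAT (adjusted p = 0.0197), NF-kappaB (0.0285), NuRD and Polycomb (0.0391), mitosis (0.0410) and ribosomal protein (0.00435) lists lay below their random lists, and the leukocyte list (0.0116) above.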

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

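The count of protein-coding genes alone and the test on matched random lists were added after seeing the data. MUC1 stayed between -4.10 and -3.90 on the log2 scale, past the threshold, under each alternative run. The number of changed genes was 13879 with DESeq2 size factors, 13977 with upper-quartile scaling, 14268 with library size alone, 14480 with no filter, 11294 with the filter of at least 1 CPM in 3 libraries, 10710 among protein-coding genes, 13149 with the DESeq2 Wald test, 14111 with limma-voom and 12807 to 13413 with 1 library left out. With library size alone 11821 of the 13957 genes kept their call and direction, and 3 were called in the opposite direction. The number changed at least 2-fold was 1357 with that filter, which tests fewer genes, and 1759 among protein-coding genes. The protein-coding counts are a part of the main result, with its adjusted p-values, and not a separate test. Lists called higher and lower numbered 8 and 6 in the main test. The numbers were 0 and 0 with an estimated correlation, 3 and 11 against matched random lists, and 11 and 11 with fry. Without DOX-negative replicate 2 they were 7 and 6. Fry ended the call of the mitochondrially encoded list (fry adjusted p = 0.0582). The cause of these differences was not tested. PDGFRB, under 1 CPM, lost its call without DOX-negative replicate 1, DOX-negative replicate 2 or DOX-positive replicate 2. Same-numbered replicates did not deviate together (correlations of -0.28, -0.02 and -0.00), so the numbers were not taken as pairs. Between different numbers the correlations ran from -0.40 (DOX-negative replicate 2, DOX-positive replicate 3) to 0.40 (DOX-negative replicate 2, DOX-positive replicate 1). A block by replicate number does not cover these. The replicate block gave 13503 changed genes (6670 higher, 6833 lower, 3089 at least 2-fold), MUC1 at -3.96, and 8 lists higher and 6 lower. Depth limits genes near 3 reads, such as SPINK1 in DOX-negative cells.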

Other observations

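Other lists fixed before the data were examined went both ways. Among 19 stemness and Notch genes 7 rose and 9 fell (camera adjusted p = 0.649). The Notch target HES1 fell 4.58-fold from 56.5 ± 3.04 to 12.3 ± 1.15 CPM, and ALDH1A3 rose 2.31-fold, ITGA6 rose 1.85-fold and CD44 rose by 0.68 on the log2 scale. Of 14 neuroendocrine genes 7 rose and 4 fell (camera adjusted p = 0.62), UCHL1, ENO2 and SYT1 rising by 0.30, 0.23 and 0.26 on the log2 scale and the neural adhesion molecule NCAM1 falling from 1.70 ± 0.299 to 0.175 ± 0.0939 CPM. Of 23 androgen receptor target genes 13 were tested, of which 9 rose and 3 fell (camera adjusted p = 0.0819, and 6 and 3 with library size alone). NDRG1, which is also on the hypoxia and glycolysis list, rose 2.01-fold, STEAP1 rose 2.23-fold and PMEPA1 fell by 0.94 on the log2 scale. Of 27 integrated stress response genes 14 rose and 11 fell (camera adjusted p = 0.62; 8 and 13 with library size alone), with SESN2 up 2.10-fold, PPP1R15A up 1.75-fold and the cystine transporter SLC7A11 down by 0.56. Of 19 unfolded protein response genes 8 rose and 5 fell (camera adjusted p = 0.602; 6 and 10 with library size alone), PDIA6 rising by 0.44 and HYOU1 falling by 0.38.

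Of 45 cytosolic ribosomal protein genes 10 rose and 13 fell (camera adjusted p = 0.844), with RPS23 up by 0.44 and RPL13 down by 0.31 on the log2 scale, and the split was 4 and 30 with library size alone and 7 and 19 with upper-quartile scaling. Of 17 leukocyte markers 5 were tested, of which 3 rose and 2 fell (camera adjusted p = 0.649): CD79A rose, and CD14 fell from 1.02 ± 0.0562 to 0.286 ± 0.0369 CPM. Of 15 fibroblast and endothelial markers 7 were tested, with 4 lower and 0 higher (camera adjusted p = 0.137), and ENG fell from 2.68 ± 0.528 to 1.23 ± 0.161 CPM. Median, mean and test differed in sign for the checkpoint, mitosis, neuroendocrine, integrated stress response and ribosomal protein lists, none of which camera called. For the mesenchymal and stemness lists camera pointed lower and fry higher (fry adjusted p = 0.011 and 0.514). Fry thus called the mesenchymal list higher, against its median log2 fold change of -0.14.

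The tests chosen only after the result was seen were both on scaling, the one on genomic DNA alone, those on a wider loss and on paralogs at the chromosome 22 block, and the count of neighbours with genes left out. The real split of the 6 libraries gave 13957 changed genes in edgeR, and the highest of the other 9 splits gave 0 (155 to 301 genes at an unadjusted p under 0.05, and 0 with limma-voom). The real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05.

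Weakly expressed genes made up most of the excess of decreases. With average log2 CPM under 1, 1807 genes fell at least 2-fold and 483 rose, while above 4 the counts were 148 and 202. Genomic DNA alone is argued against by all 11365 weakly expressed genes, whatever their change, which lost a median of 0.0266 CPM per kilobase of exon. Olfactory receptor genes, which hold little but background, lost 0.00238 (SE 0.000602) and held 0.00905 in DOX-negative cells. A gene could pass the count filter through 1 group alone, so the 11365 genes were not chosen wholly apart from their change. The 1807 genes lost 0.127, but they were selected for their fall, so that value adds no evidence. A change of scaling moves all genes alike. The median log2 fold change was -0.29 with average log2 CPM under 1 and 0.11 above 4, which argues against TMM scaling as the source of that contrast. For the ratio of decreases to increases over all genes, TMM scaling stays open. That ratio was 2.64, and 2.37 with DESeq2 size factors, which lifted the median by little. The other scalings moved genes down and could not lower it. More unspliced RNA in the DOX-negative libraries cannot be told apart from regulation. The log2 ratio of summed olfactory receptor CPM was -0.43 (SE 0.09), close to the -0.49 median of weakly expressed coding genes. That ratio cannot decide the question, because genes that hold little but background do not directly measure the unspliced RNA of other genes. Other weakly expressed types had medians of -0.31 (sense intronic), -0.30 (antisense), -0.27 (lincRNA) and 0.07 (processed pseudogenes), so not every type fell.

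SUSD2, GGT5 and POM121L9P fell together as neighbours. Loss of a wider region is argued against by CABIN1 and SPECC1L on either side, the lower of which stood at 0.14 (SE 0.04), although the median of the 14 flanking genes, -0.29 (SE 0.15), left the first test undecided. Reads shared among gamma-glutamyltransferase copies stay open for GGT5, as GGT7, at -0.36 (SE 0.09), was the only other family gene with a mean CPM of at least 1. Neighbouring coding genes both fell at least 2-fold in 176 pairs, against at most 150 in 1000 shuffles, and both rose in 54, against at most 29; with genes of like names and of the interferon and MHC lists left out, the 130 falling pairs lay within the shuffles (70 to 134) and the 29 rising pairs above them (at most 26), so a wider tendency of neighbours to fall stays open. Loss of the small block itself and shared regulation of its genes were not tested.

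CD274 rose while 35 of the 39 IFN-gamma-induced genes fell. TMM scaling is argued against, since the lowest log2 fold change of CD274 under the other scalings was 0.43. A copy-number gain in the DOX-positive cultures stays open: the 16 genes within 1 Mb had a median of 0.12 (SE 0.15), against the 0.37 set as the lower bound for a gain, with PDCD1LG2, which encodes PD-L2, at 0.91 and JAK2 at -0.65. Both were named after their values were seen. Regulation of CD274 apart from IFN-gamma signalling may also account for the rise, a hypothesis that these libraries, all exposed to IFN-gamma, cannot test.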
